A study of Mus musculus with 2 samples.

How the data were processed

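Poly(A) RNA of the small intestine was measured in 1 adult female C57BL/6J mouse, aged 10 weeks. The labels describe 1 biological replicate and 2 technical libraries of the same tissue sample. Technical replicate 1 is called the first library here and technical replicate 2 the second. Per the labels, the second library was made in 2015, after the publication to which the first belonged. RNA was extracted with a column kit for lipid-rich tissue, and both libraries carry a size range of 350 to 450, whose unit the labels do not state. The effective lengths in the deposited tables imply mean fragment lengths of 190.6 and 178.5 bases. Both libraries come from 1 animal, so no value describes variation between mice. Whether both were made from the same RNA extraction is not given in the sources used here, so a ratio between them may hold differences in sampling of the tissue as well as in library making.

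Per the file headers, each library had a gene table and a transcript table in the RSEM format, and the deposited notes give mouse assembly mm10 and gene annotation M4. The deposited notes also list separate signal tracks for the plus and the minus strand. The aligner, the quantifier's version and the read filters are not given in the sources used here. Expected counts were deposited per gene and per transcript as estimates that need not be whole, because reads that match several genes or isoforms were shared among them. TPM values were deposited as abundances corrected for effective length and scaled to a common sum in each library, per the file headers. FPKM values in the deposited gene tables were used for 1 alternative only. Isoform shares were deposited as the percent of a gene's TPM held by each transcript. The tables also held 97 spike-in entries and 26248 tRNA entries, all at 0 expected counts in both libraries, and these were left out.

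The tables held 43346 Ensembl genes. Symbols, positions and biotypes were taken from GENCODE M21 on the same assembly by matching identifiers without their version, which matched 42462 genes and left 884 with an identifier only. GC content was the mean over a gene's transcripts matched to the M21 sequences and had a value for 42721 genes. Nuclear copies of mitochondrial genes were found with BLAST 2.17.0 at 95% identity or more over 100 bases or more. Gene coordinates are on mm10 and count from 1.

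The libraries held 28277875 and 24509862 expected counts. With 1 library on each side no residual degrees of freedom were left, so edgeR's quasi-likelihood test could not be fitted. A two-sided exact binomial test was applied instead to each gene with 20 or more counts over both libraries, on expected counts rounded to whole numbers. The expected split came from TMM-scaled library sizes (edgeR 4.0.16), and genes past a Benjamini-Hochberg adjusted p of 0.05 with a difference of 2-fold or more were counted as different. That test compares these 2 libraries, not conditions, and covers counting error only, since reads without molecular identifiers are not independent molecules. Log2 ratios are second over first library with 0.5 prior counts. Where a library had 0 counts, the fold is a lower bound computed against 3 counts in that library.

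A total of 41 gene lists was fixed before the data were examined, covering cell types, organs, regional markers and pathways. The share of a list is its summed TPM as a percent of all TPM. Its level is the percentile of its median mean log2(TPM + 1) among 10000 random lists of the same size, drawn from genes at 1 TPM or more in both libraries together with the list's own members. Its shift is the percentile of its median log2 ratio among 10000 random lists matched on mean expression in 20 bins, computed for lists with 3 or more tested members. Percentiles are descriptions of these libraries, and no p-value was made from genes. Members of a list need not reach 1 TPM, so a low level follows in part from the pool of random lists. A GC trend was fitted by lowess with a span of 0.3 over tested nuclear genes, leaving out mitochondrial genes and their nuclear copies. The genes named were fixed by a rule. They were the 20 nuclear genes of highest mean TPM, counted without nuclear copies of mitochondrial genes (an exception made after the values were seen), up to 4 most abundant members of each list, members at 0 counts of lists described as low, and the sex-linked list. To these came the 10 highest and 10 lowest log2 ratios among protein-coding genes with a symbol, a mean TPM of 5 or more and an adjusted p under 0.05. For isoforms the rule took the 5 most abundant genes of the enterocyte and fat absorption lists with 2 or more expressed transcripts, and the 5 genes of largest share difference. A transcript had to reach 1 TPM in either library and its gene 10 TPM in both. Some genes chosen by the rule are withheld for evaluation and are not named in the text.

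The binomial test was tested on simulated data with the real means and library sizes. Of 15176 genes tested there, it recovered 96% of genes changed 2.5-fold upward, 98% of those changed 4-fold upward, 83.7% of those lowered to 0.4 and 89.8% of those lowered to 0.25 of their level. It called 1 unchanged gene. The simulated counts held Poisson noise only, so calls caused by GC, length or read-sharing differences between libraries were not measured. Alternatives covered the detection limit, the scaling (DESeq2 1.42.0 size factors, total counts, upper quartile), the count minimum, the fold limit, posterior mean counts, the pseudocount, the pool and matching of random lists, and each library alone. Corrections for GC content were added after seeing the data. The lists, the main settings and the other alternatives were fixed from the labels alone. Other software was Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and R 4.3.3.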

Results

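Gene expression in the small intestine of 1 adult female mouse was measured by poly(A) RNA sequencing in 2 technical libraries of the same tissue sample. The first library held 28277875 expected counts and the second 24509862. No condition was compared, so the data describe the transcripts of this tissue and how far a second library of the same sample gave the same values. Values are given as the first and then the second library, n = 2 technical libraries of 1 animal. The Xist RNA, transcribed from the inactive X chromosome, stood at 157.2 and 104.5 TPM, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in both. A count of 0 allows up to 0.106 and 0.122 CPM. Both values match the sex given in the labels. Mitochondrial protein genes and their nuclear copies held 72.0% and 21.5% of TPM, which compressed the TPM share of every other list in the first library. Log2 ratios rest on TMM-scaled counts, so a gene of similar TPM in both libraries can have a negative log2 ratio, as did Selenop (-1.41), Gzma (-1.26), Dcn (-1.24), Jchain (-1.16) and Pcna (-1.05), all higher in the first library by the exact binomial test. After removal of the GC trend these values were -0.34, -0.0587, 0.36, 1.05 and 0.66, and Jchain was higher in the second library.

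Leaving aside nuclear copies of mitochondrial genes, the nuclear transcripts of highest mean TPM included lipid carriers, antimicrobial peptides and secreted epithelial proteins. For several of them the mean rested on the second library. Apoa4, an apolipoprotein of chylomicrons, stood at 22.5 and 12533 TPM, and Apoa1 at 68.8 and 7616 TPM. The fatty acid binding proteins Fabp1 (1080 and 9783 TPM) and Fabp2 (3191 and 5248 TPM) were high in both libraries, as were the ferritin heavy chain gene Fth1 (1226 and 10744 TPM) and the selenium carrier Selenop (4787 and 5041 TPM). Reg1 stood at 3343 and 5647 TPM, B2m at 3845 and 3005 TPM, and Tpt1 at 3600 and 2553 TPM. Others were far lower in the first library than in the second, among them Rbp2 (196 and 6424 TPM), Prap1 (29.4 and 5690 TPM), Crip1 (2.64 and 4499 TPM) and the light chain constant gene Igkc (118 and 4733 TPM). Sprr2a2 reached 128 and 4751 TPM from 8710 and 49532 counts, so part of its TPM difference came from the effective length assigned to it. Apoa4 lies on chromosome 9 at 46240696 to 46243459 and Apoa1 on the same chromosome at 46228580 to 46230466, and Fabp1 lies on chromosome 6 at 71199827 to 71205023. The Apoa4 log2 ratio was 7.85 with a counting SE of 0.04, so the difference between libraries was far beyond counting error.

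At 1 TPM or more, 9147 genes were detected in both libraries, 4424 in the second alone and 244 in the first alone. Protein-coding genes made up 8632, 3897 and 140 of these. Across the 13815 genes at 1 TPM or more in either library, log2(TPM + 1) correlated with a Pearson's r of 0.628 and TPM with a Spearman's rho of 0.558. These correlations are across genes, which are not independent replicates. The median GC content was 55.8% for genes detected in the second library alone, 42.4% for those in the first alone and 48.2% for those in both.

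Enterocyte genes were abundant in both libraries. The brush border hydrolases took 0.519% and 1.00% of all TPM, and their median level was above that of every random list. Sis, the sucrase-isomaltase gene on chromosome 3 at 72888557 to 72967863, stood at 2598 and 1226 TPM, Anpep at 195 and 1555 TPM and the intestinal alkaline phosphatase gene Alpi at 44.0 and 1524 TPM. Of 20 hydrolases tested, 10 were higher in the second library, 6 were higher in the first and 4 differed by less than 2-fold. After removal of the GC trend 6 were higher in the second library and 1 in the first. Before it, all 20 passed the exact binomial test, both adjusted over the list alone and over all genes. The log2 ratio was -2.29 for Sis, at a GC content of 38.3%, and 3.84 for Alpi, at 55.0%. Of 18 genes of the microvillus and cytoskeleton, 11 were higher in the second library, including Lgals4 (34.3 and 2279 TPM) and Krt8 (15.5 and 1307 TPM), and 3 were higher in the first, against 7 and 4 after removal of the GC trend. Pls1, an actin bundler, was higher in the first before that removal, with a log2 ratio of -1.53, at 730 and 643 TPM. Krt20, a keratin of mature enterocytes, stood at 252 and 1111 TPM with a log2 ratio of 0.86, a difference of less than 2-fold.

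Genes of fat absorption took 0.75% and 4.63% of TPM, and 1.89% and 4.32% of counts. Of 24 tested, 15 were higher in the second library, 3 were higher in the first and 6 differed by less than 2-fold, with a median log2 ratio of 2.44. After removal of the GC trend 9 were higher in the second library and 3 in the first, with a median of 0.47. Iron, calcium and vitamin genes took 0.198% and 2.10%, led by Fth1, Rbp2, a retinol binding protein, and the ferritin light chain gene Ftl1 (1.81 and 1380 TPM). S100g, a calcium buffer, stood at 260 and 744 TPM, and of 18 tested members 9 were higher in the second library and 3 in the first. With the GC trend removed, 5 of them were higher in the second library and 1 in the first. Sugar, amino acid and peptide transporters took 0.115% and 0.275%, with the sodium-glucose cotransporter Slc5a1 at 344 and 652 TPM, Slc2a2 at 212 and 242 TPM and Slc6a19 at 80.6 and 240.4 TPM. Of 16 transporters, 7 were higher in the second library, 2 were higher in the first, among them Slc6a20a by its log2 ratio of -1.21, and 7 differed by less than 2-fold. After removal of the GC trend these counts were 2 in the second library and 3 in the first.

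Drug-metabolising enzymes took 1.21% and 1.56% of TPM, and 2.32% and 2.00% of counts. Cyp3a11, the main drug-oxidising P450 of this list, stood at 3416 and 2301 TPM, Cyp3a13 at 1034 and 759 TPM, Sult1b1 at 1185 and 612 TPM and Gsta1 at 968 and 2084 TPM. Of 24 enzymes, 11 were higher in the first library, 7 in the second and 6 differed by less than 2-fold. After removal of the GC trend 6 were higher in the second library and 0 in the first. Their median log2 ratio was -0.19 against 0.26 for all tested genes, and lay at the 95.1st percentile of random lists matched on expression.

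**Figure D1:**
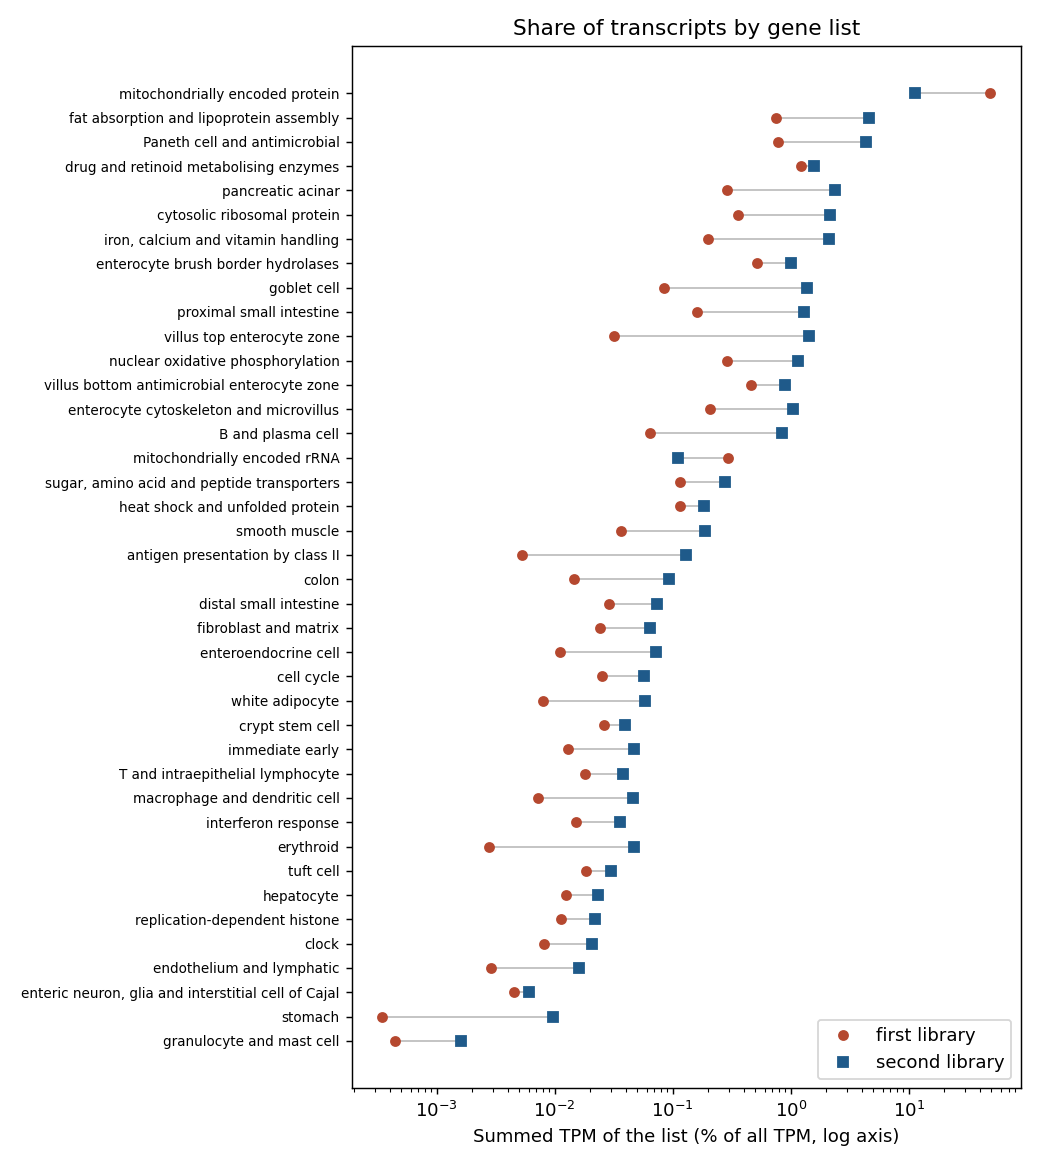
Summed TPM of each gene list as a percent of all TPM (log axis) in the first library (circles) and the second library (squares), with 1 line joining the 2 values of a list. Mitochondrially encoded protein genes fall from 48.9% to 11.2%, fat absorption genes lie at 0.75% and 4.63%, and stomach genes in the first library and granulocyte and mast cell genes in the second are lowest.

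Secretory epithelial genes were present in both libraries. The Paneth cell and antimicrobial list took 0.787% and 4.30% of TPM, and 0.399% and 1.20% of counts, led by the alpha-defensin genes Defa24 (475 and 11074 TPM), Defa3 (67.5 and 7548 TPM) and Defa23 (44.5 and 7035 TPM) and by Reg1. Without the colipase gene Clps the list took 0.787% and 4.14% of TPM. Of 21 members, 12 were higher in the second library and 1 in the first. The alpha-defensin genes are near-identical copies on chromosome 8, so the count of each single gene is uncertain. Goblet cell genes took 0.0840% and 1.38% of TPM, and 0.139% and 1.06% of counts, with Zg16 at 98.8 and 5584 TPM, the trefoil peptide gene Tff3 at 2.89 and 2774 TPM, the mucus protein gene Fcgbp at 3.42 and 1463 TPM and the membrane mucin gene Muc13 at 231 and 940.3 TPM. Of 15 tested, 8 were higher in the second library and none in the first, and 14 passed the exact binomial test at any fold.

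Rarer epithelial cells were seen at lower levels. Enteroendocrine genes took 0.0111% and 0.0716%, with the hormone genes Gip at 0.150 and 162 TPM, Sst at 9.16 and 94.4 TPM, Ghrl at 0 and 82.6 TPM and the granule gene Chgb at 12.6 and 78.3 TPM. Ghrl had 0 and 544 counts and was at least 117-fold higher in the second library. Tuft cell genes, 6 of 16 at 1 TPM or more in both libraries, had a median level at the 0.02nd percentile of random lists. They took 0.0184% and 0.0301% of TPM. Cd24a stood at 149 and 99.0 TPM and made up most of that share in the first library. Rgs13 stood at 16.9 and 5.25 TPM and Ptgs1 at 6.44 and 18.2 TPM. Alox5ap had 4 and 108 counts, which gave 0.200 and 104 TPM, so its TPM rested largely on the effective length assigned. Cd24a and Alox5ap together made up most of the tuft cell share in the second library, so both shares rested on few genes. Crypt stem cell genes took 0.0259% and 0.0390%, led by Olfm4 at 156 and 204 TPM, Slc12a2 at 47.1 and 27.8 TPM, Cdca7 at 9.32 and 30.8 TPM and Smoc2 at 4.53 and 28.9 TPM. Cell cycle genes took 0.0254% and 0.0565%, with Pcna at 95.4 and 94.2 TPM, Stmn1 at 20.1 and 74.2 TPM, Top2a at 19.3 and 39.4 TPM and Ccna2 at 31.4 and 20.2 TPM.

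Transcripts of antibody-secreting cells dominated the immune lists. B and plasma cell genes took 0.0638% and 0.844%, of which Igkc and the IgA heavy chain gene Igha (5.59 and 2951 TPM) made up most in the second library. Jchain, which joins IgA subunits, stood at 443 and 477 TPM and Xbp1 at 52.7 and 150 TPM. Igha lies on chromosome 12 at 113254830 to 113260236, has a GC content of 53.9% and had 168 and 51352 counts. Jchain, at 38.8%, had 15758 and 10899 counts. Of 18 members, 13 were higher in the second library and 4 in the first, against 8 and 1 after removal of the GC trend. T and intraepithelial lymphocyte genes took 0.0182% and 0.0377%, with the granzyme genes Gzma at 131 TPM in both and Gzmb at 19.4 and 43.0 TPM, Ccl5 at 4.21 and 86.3 TPM and Cd7 at 2.34 and 34.2 TPM. Macrophage and dendritic genes took 0.00728% and 0.0459%, with Lyz2 at 22.4 and 135 TPM and the complement genes C1qa, C1qb and C1qc at 0.440, 0.0800 and 0.930 TPM in the first library and 72.7, 65.0 and 57.7 TPM in the second. Of the 10 class II antigen presentation genes 9 were higher in the second library, led by Cd74 (2.40 and 513 TPM) and H2-Ab1 (10.2 and 256 TPM). H2-Aa stood at 32.5 and 246 TPM and H2-Eb1 at 0.650 and 207 TPM. Granulocyte and mast cell genes were low, at 0.000442% and 0.00161%. Kit and Mcpt1 stayed under 5 TPM in both libraries, Siglece and Prg2 reached 2.95 and 2.65 TPM in the second, and Ly6g, Mpo, Elane and Epx had 0 counts in both.

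Muscle and connective tissue genes differed between libraries to unequal degrees. Smooth muscle genes took 0.0362% and 0.186%, and 13 of 19 tested were higher in the second library against 2 higher in the first. Tpm1 stood at 193 and 415 TPM, the smooth muscle actin gene Acta2 at 10.1 and 227 TPM, Myl9 at 0.400 and 227 TPM and Tpm2 at 5.34 and 160 TPM. Fibroblast and matrix genes took 0.0243% and 0.0644%, with 9 of 20 higher in the second library and 4 in the first, and 2 and 5 after removal of the GC trend. Dcn stood at 86.0 and 87.3 TPM, Col3a1 at 44.7 and 75.7 TPM, Sparc at 19.4 and 69.8 TPM and Fbln1 at 4.11 and 145 TPM. Endothelial genes took 0.00288% and 0.0161%, with Plvap at 0.570 and 54.8 TPM, Egfl7 at 0.270 and 23.2 TPM, Pecam1 at 1.93 and 14.8 TPM and Emcn at 9.11 and 10.1 TPM. Genes of enteric neurons, glia and interstitial cells were low, at 0.00453% and 0.00607%, led by the neuropeptide gene Vip at 28.4 and 19.1 TPM. Snap25 stood at 5.17 and 4.0 TPM, Etv1 at 2.60 and 3.24 TPM and Uchl1 at 0.210 and 8.76 TPM. Erythroid genes took 0.00277% and 0.0469%, with the haemoglobin genes Hbb-bs at 5.56 and 148 TPM, Hba-a2 at 0.460 and 124 TPM and Hba-a1 at 0 and 84.7 TPM, and with Bpgm at 12.3 and 53.9 TPM.

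Markers of other organs were also measured. Pancreatic acinar genes took 0.421% and 1.46% of counts. They took 0.290% and 2.35% of TPM, and 0.280% and 1.79% without Zg16, which goblet cells also express. Amylase Amy2a5 stood at 1355 and 1821 TPM, the elastase gene Cela2a at 137 and 3441 TPM and the chymotrypsinogen gene Ctrb1 at 12.5 and 2243 TPM. Of 19 acinar genes tested, 15 were higher in the second library, 1 was higher in the first and 3 differed by less than 2-fold. Amy2a5 has a GC content of 38.8%, Cela2a of 52.1% and Ctrb1 of 57.6%. Hepatocyte genes took 0.0125% and 0.0234%, of which Cps1, also an intestinal enzyme, gave most at 109 and 159 TPM. Trf stood at 7.94 and 46.5 TPM, Cyp2e1 at 4.66 and 10.8 TPM and Ttr at 0.530 and 4.64 TPM, while Ahsg had 0 counts in both. White adipocyte genes took 0.00796% and 0.0585%, with Fabp4 at 30.6 and 105 TPM, Pck1 at 18.8 and 81.6 TPM, Pnpla2 at 0.620 and 104 TPM and Cidec at 0.550 and 103 TPM. Stomach genes were low, at 0.000347% and 0.00965%. Tff2 stood at 3.08 and 81.1 TPM and Gkn3 at 0.1 and 13.5 TPM, Pgc and Gif stayed under 2 TPM, and Muc5ac, Muc6, Atp4b, Tff1, Gkn2 and Chia1 had 0 counts in both. Colon genes took 0.0144% and 0.0936%. Most of that in the second library was Sycn (0.280 and 675 TPM), which the acinar list also holds. Slc26a3 stood at 106 and 89.6 TPM, Car4 at 23.4 and 108 TPM and Aqp8 at 2.0 and 29.7 TPM, and Hoxd10 and Hoxd13 had 0 counts.

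The labels do not say which segment was sampled, so proximal and distal markers were set side by side. The 15 proximal genes had a median mean log2(TPM + 1) of 5.0 and the 14 distal genes one of 2.71, a difference of 2.29. Taken alone, the first library gave 3.11 and the second 2.33. Fabp1, Adh6a (206 and 890.0 TPM), Cyp2b10 (164 and 616 TPM) and lactase, Lct (30.3 and 517 TPM), led the proximal list, whose level lay at the 99.1st percentile. Slc26a3, the bile acid exporter genes Slc51a (1.94 and 148 TPM) and Slc51b (50.9 and 140 TPM), and Reg3g (96.2 and 119 TPM) led the distal list, and Fgf15, a hormone of the ileum, had 0 counts in both. Genes of the lower villus took 0.465% and 0.899%, most of it Reg1 (3343 and 5647 TPM) in both libraries. Lypd8 stood at 179 and 1611 TPM, Ccl25 at 404 and 726 TPM and Reg3b at 178 and 568 TPM. Genes of the villus top took 0.0319% and 1.42%, nearly all of it Apoa4 in the second library, with Ada at 30.2 and 849 TPM, Creb3l3 at 8.06 and 258 TPM and Cdh1 at 77.0 and 161 TPM. The median log2 ratios of the zone lists were -0.42 and -0.10 against 0.26 for all tested genes, and lay at the 74.5th and 80.7th percentile of random lists matched on expression.

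Response genes differed widely in level, from the 0.02nd percentile of random lists for clock genes to the 94.0th for heat shock genes. Of 16 clock genes, 9 reached 1 TPM in both libraries, a limit that the other genes of the random pool had to pass. The low percentile follows in part from that. Interferon response genes took 0.0153% and 0.0359%, with Irf7 at 26.7 and 80.0 TPM, Oasl2 at 26.3 and 64.0 TPM and Ifit1 at 26.0 and 27.7 TPM. Of 15 tested, 4 were higher in each library and 7 differed by less than 2-fold. Immediate early genes took 0.0130% and 0.0470%, with Fos at 29.6 and 75.4 TPM, Zfp36 at 19.2 and 121 TPM, Klf6 at 56.2 and 42.1 TPM and Junb at 0.450 and 55.3 TPM. The chaperone genes Hspa8 (247 and 873 TPM), Hspa5 (272 and 290.3 TPM), Hsp90b1 (307 and 222 TPM) and Hsp90aa1 (189 and 85.9 TPM) led the heat shock list at 0.116% and 0.183%. Clock genes took 0.00818% and 0.0206%, with Nr1d1 at 0.820 and 68.7 TPM, Nr1d2 at 32.0 and 19.2 TPM, Clock at 21.6 and 17.6 TPM and Arntl at 9.97 and 20.6 TPM. Replication-dependent histone genes, whose messages largely lack a poly(A) tail, were low at 0.0112% and 0.0220%. Hist1h2bc stood at 107 and 175 TPM and Hist1h1c at 4.24 and 36.5 TPM, Hist1h4i and Hist1h4d stayed under 5 TPM, and Hist1h2ab and Hist2h2ac had 0 counts.

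Mitochondrially encoded transcripts took the largest share of both libraries. The 13 protein genes held 48.9% and 11.2% of TPM and 30.8% and 6.10% of counts (Wilson 95% intervals 30.74% to 30.78% and 6.09% to 6.11%, covering counting error only). mt-Atp8 stood at 188957 and 41881 TPM, a level inflated by an effective length of 35.8 bases, and mt-Co1 at 91767 and 29311 TPM. mt-Cytb reached 36627 and 11650 TPM and mt-Nd1 32615 and 8873 TPM. All 13 were higher in the first library in the exact binomial test, with a median log2 ratio of -3.14. The ribosomal RNA genes mt-Rnr1 (1131 and 509 TPM) and mt-Rnr2 (1819 and 599 TPM) were also higher in the first. Values of single genes are uncertain, because 7 nuclear pseudogenes on chromosome 1 between 24611535 and 24616197 match them at 99.7% identity or more over whole aligned stretches. Among these, Gm28661 and Gm10925 were listed at 55454 and 28039 TPM and at 72736 and 20107 TPM. Gm28437 stood at 49094 and 22883 TPM, Gm10222 at 25074 and 7984 TPM, Gm28438 at 21048 and 6941 TPM, Gm29216 at 354 and 16537 TPM and Gm28439 at 7554 and 1.26 TPM. Together the 13 genes and the nuclear copies held 41.6% and 9.58% of counts, 4.34-fold more in the first library.

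Nuclear genes of oxidative phosphorylation went the other way, at 0.287% and 1.15% of TPM. Of 22 tested, 12 were higher in the second library and 1 in the first. Atp5b stood at 224 and 1795 TPM, Atp5a1 at 367 and 873 TPM, Ndufa4 at 511 and 905 TPM and Cox6c at 417 and 978 TPM. Their log2 ratios were 1.72, 1.22, -0.40 and -0.10, so Ndufa4 and Cox6c were not higher in the second library on TMM-scaled counts. Cytosolic ribosomal protein genes took 0.357% and 2.15%, and 21 of 28 were higher in the second library with none higher in the first. Rps24 stood at 1455 and 1612 TPM, Rpl10 at 174 and 946 TPM, Rps12 at 44.1 and 1520 TPM and Rplp1 at 9.40 and 2215 TPM. Within this list TPM ran from 0.440 to 1455 in the first library and from 211 to 2215 in the second. The SD of log2 TPM was 2.86 in the first and 0.70 in the second, and Spearman's rho of TPM with GC content across the 28 genes was -0.697 and 0.245.

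**Figure D2:**
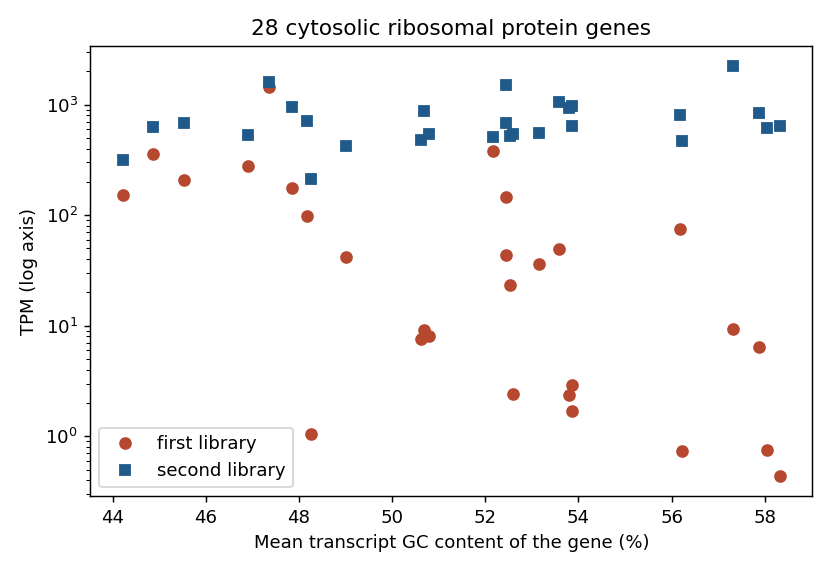
TPM (log axis) of 28 cytosolic ribosomal protein genes against their mean transcript GC content in percent, for the first library (circles) and the second library (squares). Values of the second library stay between 211 and 2215 TPM, and those of the first run from 0.440 to 1455 TPM and are lower at higher GC content.

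Differences of this kind ran through the whole transcriptome. Of 15194 genes tested, 13432 (88.4%) passed the exact binomial test at any fold, and 10261 (67.5%) did so with a difference of 2-fold or more. With TMM scaling 6101 were higher in the second library and 4160 in the first, and with total counts 7800 and 1520. The median log2 ratio of all tested genes was 0.26 with TMM, 0.10 with DESeq2 size factors, 0.06 with the upper quartile and 1.10 with total counts, and list medians are to be read relative to these. In the highest of 10 expression bins, the robust SD of the log2 ratio was 1.30, against 0.03 from binomial sampling alone. In the lowest bin these were 2.70 and 0.49. No replicate check of these differences was possible, since each side is 1 library.

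The log2 ratio rose with GC content, with a Spearman's rho of 0.855 across 15127 nuclear genes. The median was -2.48 below 38% GC, -0.43 at 46 to 50%, 3.26 at 54 to 58% and 5.14 at 58% or more. Of 2149 protein-coding genes at 58% GC or more, 189 were at 1 TPM or more in the first library and 1353 in the second. Across protein-coding genes tested, rho between GC content and TPM was -0.586 in the first library and 0.070 in the second. Of 39 lists tested, 15 had a median log2 ratio above and 1 below the central 95% of random lists matched on expression. The latter was the mitochondrial protein list. After removal of the GC trend, a correction chosen after seeing the data, the balance of higher and lower members turned toward the first library for transporter, crypt stem cell, fibroblast, enteric neuron, villus top, immediate early, heat shock and clock genes. It turned toward the second for drug-metabolising enzymes. Matched on GC as well, the brush border (87.7th percentile), microvillus (70.0th), fat absorption (86.4th) and iron and vitamin (88.2nd) lists came back inside the central 95%. The drug-metabolising (99.05th), cell cycle (99.3rd) and T cell (99.9th) lists newly lay above it. The crypt stem cell (1.28th) and clock (0.97th) lists newly lay below. Paneth cell, pancreatic acinar and ribosomal protein lists stayed above, at the 100th percentile. Of 38 lists matched this way, 16 lay outside. Matched on length too, 11 did. The drug-metabolising (94.1st percentile), cell cycle (96.9th), crypt stem cell (5.02nd) and clock (2.955th) lists then came back inside. The T cell list stayed above, at the 98.9th. Of 600 tested list members, 561 passed the test adjusted over the list alone and 561 over all genes, with 315 higher in the second library and 107 in the first.

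**Figure D3:**
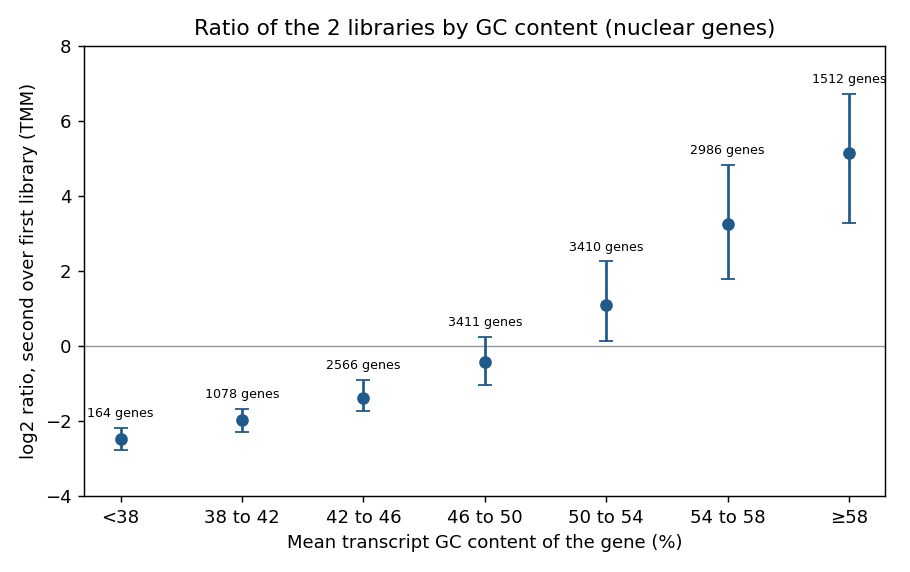
Median log2 ratio of the second over the first library (points, TMM scaling) with quartiles (bars) for tested nuclear genes in 7 bins of mean transcript GC content in percent. The median rises from -2.48 below 38% to 5.14 at 58% or more.

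The genes with the highest ratios were nearly absent from the first library. Gm7849, on chromosome 8 at 21455445 to 21456560 among the alpha-defensin genes, had 0 and 10641 counts and was at least 2287-fold higher, with a value that sharing of reads among defensin copies makes uncertain. Sbno2 (0 and 1664 counts, at least 358-fold), Hspg2, which encodes the basement membrane protein perlecan (0 and 1620 counts, at least 348-fold), and Mcrs1 (0 and 1243 counts, at least 267-fold) came next. Apba3, Pex16, Capn15, Gm20605 and Mbd3 also had 0 counts in the first library and were at least 239, 234, 223, 203 and 188-fold higher in the second. Naprt had 1 and 3656 counts, a log2 ratio of 10.62 with a counting SE of 1.18. All of these but Gm7849 had a GC content of 57.5% or more. At the other end, Defa31 (8288 and 3 counts) and Defa2 (50 and 0 counts) belong to the same defensin cluster and are equally uncertain. mt-Co2, mt-Co3, mt-Atp6, mt-Nd2, mt-Nd5 and mt-Atp8 had log2 ratios of -6.12, -4.61, -4.50, -3.60, -3.18 and -3.19. The first 3 of these values are uncertain too, because the split of reads with nuclear copies of 100% identity can move them. Those copies, Gm28661, Gm28437 and Gm10925, had log2 ratios of -2.23, -2.36 and -3.10. Gm6710 (-4.15) and 2210418O10Rik (-3.21), both on chromosome 2, completed the 10 lowest.

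Isoform shares differed between the libraries as well. Of 2269 genes with 2 or more expressed transcripts, 1400 (61.7%) had the same most abundant transcript in both libraries. The largest difference of a transcript's share within a gene had a median of 25.9 percentage points, and it was 50 points or more in 491 genes. Of 1075 genes with one transcript gaining and another losing 20 percentage points or more, the gaining one had the higher GC content in 895 (83.3%). Apoa1 (95.6% and 97.3%), Anpep (99.8% and 98.0%) and Apob (60.1% and 68.0%) kept their leading transcript. In Sis the leading transcript of the first library, of 772 bases, held 42.1% and 38.6%, while one of 5953 bases held 26.6% and 52.2%. In Lgals4 a transcript of 1059 bases went from 71.8% in the first library to 5.83% in the second, and one of 1384 bases held 11.7% and 91.0%. In Mxi1, Cmip, Gng10, Nxt2 and Ighv1-9 the leading transcript of one library was at 0% in the other, at gene levels between 10.8 and 114 TPM.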

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

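The GC corrections were chosen after seeing the data, and the other settings before the data were examined. No paired analysis was possible because the series holds 1 group. With 2 libraries, each share lies within 1 SD of their mean by arithmetic, so agreement of 1 library with the mean shows nothing. The values of each library alone show the spread. They were 48.9% and 11.2% for mitochondrial protein genes, 0.75% and 4.63% for fat absorption and 0.290% and 2.35% for pancreatic acinar genes. Mean shares moved by more than 1 SD in 14 of 41 lists on counts, in 6 of 39 without mitochondrially encoded genes and in none with posterior mean TPM. Leaving out mitochondrially encoded genes kept their nuclear copies, 23.1% and 10.2% of TPM, so it lifted the compression only in part. Genes detected in both libraries numbered 14187 at 0.1 TPM and 3431 at 10 TPM against 9147, and single libraries gave 9391 to 13571. Differing genes numbered 5767 at a 4-fold limit and 5280 after removal of the GC trend, against 10261. Of the latter, 3086 were called the same way in both fits. The other 9 settings gave 8422 to 13432. Pearson's r of 0.628 became 0.579 with a pseudocount of 0.1, 0.656 with 5, 0.822 over all genes, 0.444 over genes at 10 TPM or more and 0.666 on CPM. The proximal and distal difference ran from 2.33 to 3.11 in single libraries. The same leading isoform was seen in 53.3% of genes at 1 TPM against 61.7%. The cause was not tested for these changes, except that the limits on level and fold change the genes counted.

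Of 178 named genes tested, none changed sign in a call under DESeq2 size factors, total counts, upper quartile or posterior mean counts. With total counts 21 lost their call, among them Pls1 at -0.69 and Slc6a20a at -0.37, and 16 gained one. Among genes that kept their sign, removing the GC trend ended the call of 31 and gave one to 5. A further 27, with a call before or after that removal, changed sign. Their GC content was 44.2% or less or 53.9% or more. Among them, the values after removal were 1.37 for Amy2a5, -1.94 for Anpep, 0.23 for B2m, -0.66 for Car4, -0.75 for Chgb, 0.11 for Clock, 0.0228 for Cyp3a11, 0.36 for Dcn and 0.33 for Emcn. They were 1.10 for Fabp2, -2.79 for Fos, -0.93 for Hist1h1c, 0.30 for Ifit1, -1.56 for Irf7, 1.05 for Jchain, -0.35 for Junb, -1.46 for Pck1, 0.66 for Pcna and -0.10 for Plvap. They were -1.20 for Sst, 0.13 for Sult1b1, -0.0632 for Tpm2, -0.88 for Uchl1, -0.81 for Zfp36, 0.0135 for mt-Atp8 and 0.23 for mt-Rnr1. Of these genes, Anpep, Irf7, Jchain and Sst took an opposite call, and Amy2a5, Fabp2, Fos and Pck1 gained one. The others named here kept no call. Over the lists, 19 of 229 shift values and 16 of 164 level values came back inside the central 95%, 8 and 17 left it, and none crossed to the other side. Against 30 as reported, 26 lists lay outside on level with random lists from all genes with a count, 20 on the same side. Setting genes at 0 counts to their bound moved 2 list medians, by 0.21 at most. Depth limits statements on genes near 3 counts.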

Other observations

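The test of shared mitochondrial reads, the list matching that added length, the separate count of process lists, and the gene families in the next paragraph were chosen after the values were seen. The other tests and their bounds were written down before GC content, length or the second acinar list had been compared with the values. By then TPM values, library ratios and list shares had already been looked at, so the patterns themselves were chosen after seeing the data.

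Further gene families were described without a test. Among 8 immunoglobulin heavy chain constant genes, Igha made up 2951 of 3019 TPM in the second library, followed by Ighm at 43.3 TPM and Ighg2b at 8.96 TPM, while the first library held 15.2 TPM in all. Of 23 claudin genes, which encode tight junction proteins, 8 reached 1 TPM in the second library, led by Cldn7 (38.1 and 541 TPM), Cldn15 (25.9 and 491 TPM) and Cldn3 (0.190 and 274 TPM). Of 50 keratin genes the simple epithelial Krt8, Krt20, Krt19 and Krt18 stood at 1307, 1111, 595 and 97.1 TPM in the second library, and at 15.5, 252, 2.71 and 0.390 TPM in the first. Of 39 Hox genes 9 reached 1 TPM in the second library, with Hoxa4 (0.820 and 3.0 TPM), Hoxb2 (1.16 and 2.93 TPM) and Hoxa5 (1.78 and 2.87 TPM) highest, and Hoxd10, Hoxd11, Hoxd12, Hoxd13, Hoxa13, Hoxb13 and Hoxc13 had 0 counts in both. The 22 alpha-defensin genes summed to 5384 and 32701 TPM. Single members moved apart within that sum, with Defa17 at 1889 and 783 TPM and Defa24 at 475 and 11074 TPM.

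The first pattern is the difference of nuclear genes between libraries beyond counting error. A GC bias that differs between the libraries is a candidate explanation, since the GC trend removed 66.4% of the variance of the log2 ratio. The trend leaves a part over, because 5280 genes differed by 2-fold or more after its removal, 3086 of them in the same direction as before. It used the mean GC content over a gene's transcripts, not that of the transcripts expressed. With the GC content of the longest transcript, Spearman's rho with the log2 ratio was 0.874 against 0.855. What is left over may thus still hold GC bias. A length bias may add to it, since the rest correlated with effective length at a Spearman's rho of -0.307, just past the bound of 0.3 set for it. Whether the mix of cell types differed stays open. Outside random lists matched on expression and GC lay 16 of 38 lists, 14 above and 2 below (11 in all with length matched too). That count was past the bound set beforehand for a mix. A comparison added after the values were seen put 3 of 7 lists of processes that run in any cell type outside. Of the remaining lists, 13 of 31 lay outside. The process lists thus lay outside about as often, so the count does not measure a mix. Such a mix would not by itself spread ribosomal protein genes, which every cell uses, over an SD of 2.86 in the first library against 0.70 in the second. No biological difference between groups could be tested, because the design holds 1 group.

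The second pattern is the larger mitochondrial share of the first library. Sharing of reads with nuclear copies is argued against, since the 13 genes and the copies together still differed 4.34-fold in their share of counts. A GC bias stays open as a candidate, because the 13 genes, with a median GC content of 37.1%, lay a median of -0.76 from the nuclear trend at their own GC content, with a median absolute deviation of 0.44. Their log2 ratio was -3.14 and the trend at their GC content -2.45. The 6 genes without an abundant nuclear copy gave -0.74. Whether more mitochondrial RNA entered the first library remains open. The trend comes from nuclear genes, and all 13 genes lie at 31.9% to 41.1% GC, so the part at the trend does not exclude it.

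The third pattern is the presence of pancreatic acinar transcripts. Pancreatic tissue attached to the sample is a candidate explanation, since 88.9% of a second list of 18 acinar genes reached 1 TPM in the second library, among them the acinar transcription factor gene Rbpjl (0.440 and 9.15 TPM), and 9 of 18 in the first. Spink1 (357 and 2260 TPM), Pnliprp2 (34.0 and 81.0 TPM) and Gp2 (19.2 and 60.4 TPM) were its most abundant members, while Ptf1a stayed at 0.320 TPM. Of all protein-coding genes, 2711 of 4479 at 46 to 50% GC and 2651 of 3872 at 54 to 58% reached 1 TPM in the second library. Detection at that level is thus weak support. Of that list Gp2, Nr5a2 and Bhlha15 are also known from intestinal epithelium. Of 8 islet genes 4 reached 1 TPM in the second library and 1 in the first, with Ins2 at 49.0 TPM and Ins1 at 6.65 TPM, both at 0 counts in the first, and Iapp at 4.11 and 6.98 TPM. Expression of the acinar genes, Spink1 and Pnliprp2 among them, and of the islet genes by the intestine itself was not excluded.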
